A study of Rhodopseudomonas palustris CGA009 with 3 samples.

How the data were processed

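The series holds 3 RNA-seq libraries of *Rhodopseudomonas palustris* CGA009, a purple non-sulfur bacterium that grows in light without oxygen: 2 from the wild type and 1 from a couR mutant. Per the labels' protocols, cells grew anaerobically in light with 10 mM succinate at 30 °C and were harvested at an optical density at 660 nm of 0.5. Total RNA was treated with DNase, and both cDNA strands were primed with not-so-random primers, a selected set of short primers, before PCR amplification. Groups and the wild-type replicate numbers were taken from the sample titles. The mutant title gives no number, and its replicate number of 1 was assigned here. Nothing in the labels says that the wild-type libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

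The authors deposited 1 line per aligned read, with start, end, strand and a mapping quality, on the EMBL chromosome sequence BX571963.1. The deposited score of each read is this mapping quality, which ran from 0 to 37 and is 0 where a read has equally good places. Per the submitters' processing notes, BWA and DESeq were used. Their versions, roles and parameters, and any filter on reads, are not given in the sources used here. Read names showed 1 flow cell and 3 lanes, with 1 lane per library, so lane and genotype cannot be told apart. Reads were 29 to 33 bases long, and 99.6% had 31 bases. The depth was 8470853 reads for wild type 1, 10462133 for wild type 2 and 8413619 for the mutant. The labels describe no molecular identifiers for the PCR reads, so all intervals on shares cover counting error only.

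The only gene table used here belongs to assembly ASM19577v2, whose coordinates are not those of the reads. It held 5041 genes, and no symbol in it was couR, couA or couB. Reads were therefore not assigned to genes, and the alternative fixed for this case was used: windows of 500 bp on each strand, with a read counted where its midpoint lay. The couR level, the coumarate locus list, the other lists among the 23 gene lists fixed beforehand and the share of reads on the sense strand were not analysed here.

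Windows with more than 50% of their pooled reads at mapping quality 0 were called repeated and left out of tests and library sizes, a choice made after the data were examined. They were 134 of 21838 windows. Of the rest, windows with at least 10 reads in 1 library and at least 15 over the 3 libraries were tested, which left 9287. Libraries were scaled by the trimmed mean of M values (TMM, trimming 30% of the M values and 5% of the A values), with factors of 0.928 for wild type 1, 1.14 for wild type 2 and 0.947 for the mutant. Levels are given as RPM, the reads per 1000000 reads outside repeated windows after this scaling.

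The main test was planned as a quasi-likelihood test on counts per gene. That test was kept for tables deposited as counts, and here the deposited lines are reads. The read totals per window, counted here, were tested with limma-voom in its place (limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. The fit had 1 residual degree of freedom, from the wild-type pair. The prior degrees of freedom were infinite, so every window took its spread from the trend across windows, and the lone mutant library was assumed to vary like the wild type. Neighbouring windows of a transcript are not independent. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work. Wilson intervals at 95% were used for shares of reads.

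The rule for naming windows was fixed before the data were examined. It took up to 12 called windows per direction by log2 fold change, with at least 50 reads in 1 library and both wild-type libraries on the same side of the mutant. Where fewer than 5 were called in a direction, the smallest p-values filled up to 5. Called windows at most 5000 bp apart, on either strand, were joined into loci.

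The test was checked on simulated read totals for the mutant against both wild-type libraries, with 200 changed windows beside 9087 unchanged ones. Its dispersion, 0.0311, was a trimmed mean over windows; a first version of the check used a median, which is too low with 2 replicates, and was replaced after its result was seen. Of the simulated increases, limma-voom called 6 of 34 at 2-fold, 32 of 33 at 4-fold and 33 of 33 at 8-fold. Of the simulated decreases it called 8 of 33 at 2-fold, 18 of 34 at 4-fold and 12 of 33 at 8-fold, with 1 false call. Alternatives covered scaling, filters, strand, read assignment, repeated positions, mapping quality, leaving out each wild-type library and, chosen after seeing the data, other tests, window sizes, window positions, scaling without TMM and a filter of at least 30 reads in 1 library.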

Results

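RNA-seq reads were compared between wild-type *R. palustris* CGA009 (2 libraries) and a couR mutant (1 library), all grown on succinate in light. CouR is a transcriptional regulator, and the stated purpose of the series was to find the genes it regulates, under a title that names p-coumarate degradation. p-Coumarate is an aromatic acid from plant lignin. Most reads fell in repeated sequence, at 68.0% in wild type 1 (95% Wilson interval 67.99% to 68.05%), 67.4% in wild type 2 (67.35% to 67.41%) and 73.0% in the mutant (73.01% to 73.07%). Nearly all of these lay at 2 loci, 4992001 to 4998000 and 5246001 to 5252000. Outside repeated sequence, 2709061, 3412963 and 2268637 reads remained for wild type 1, wild type 2 and the mutant. They lay at 124474, 139593 and 111301 distinct positions, or 21.8, 24.4 and 20.4 reads per position.

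The wild-type libraries were compared first, to set the scale of differences between libraries of 1 genotype. Across 9287 windows, which are not independent replicates, their log2(RPM + 1) values had a Pearson r of 0.953 and a Spearman rho of 0.917. For the mutant these were 0.951 and 0.921 with wild type 1 and 0.947 and 0.915 with wild type 2. Of the 4200 windows with at least 50 reads in 1 library, 138 differed at least 2-fold between the wild-type libraries, more than the 101 between wild type 1 and the mutant and fewer than the 167 between wild type 2 and the mutant. At the 4-fold level, the wild-type libraries differed in 2 windows. The mutant differed at least 4-fold from wild type 1 in 24 of these windows, all higher in the mutant. It differed at least 4-fold from wild type 2 in 25, of which 23 were higher and 2 lower.

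The comparison of the mutant with the wild type addressed which parts of the chromosome change when couR is mutated. Reads rose in the mutant in 27 of 9287 windows (limma-voom, adjusted p under 0.05), and 25 of the 27 lay at 2 loci. One locus, 1997501 to 2011000 on BX571963.1, held 21 called windows, 14 on the minus strand and 7 on the plus strand. The other, 4742001 to 4744000, held 4 called windows, all on the minus strand. Which genes these positions cover was not analysed here.

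**Figure D1:**
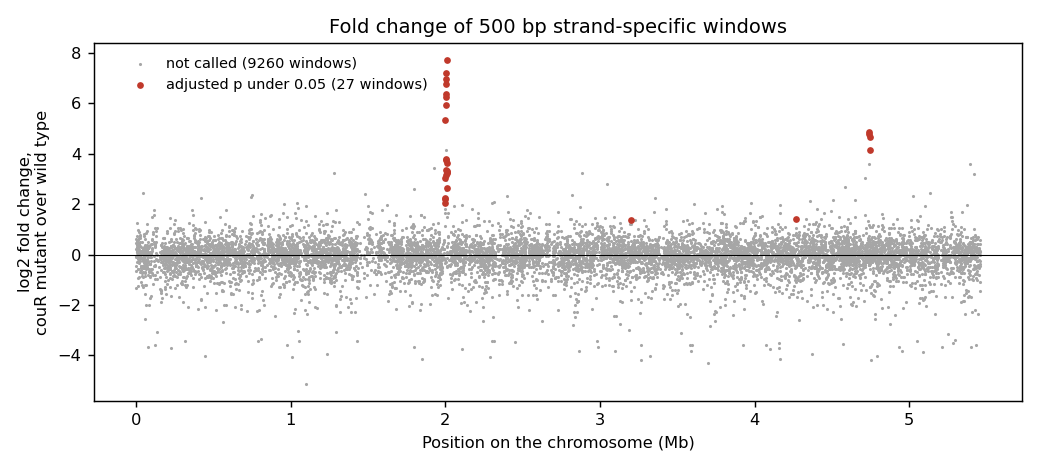
Each point is a 500 bp window on 1 strand, placed by its position on the chromosome in Mb (x axis) and its limma-voom log2 fold change of the couR mutant over the wild type (y axis). Red points are the 27 windows with an adjusted p under 0.05, 25 of them in 2 stacks near 2.0 and 4.7 Mb, and grey points are the other 9260 tested windows.

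At the larger locus, 3 stretches of windows rose. On the minus strand from 2000501 to 2006000, all 11 windows rose, and their reads together went from 184.7 ± 5.64 RPM in the wild type (SD, n = 2) to 3805 RPM in the mutant, 20.6-fold higher. On the plus strand from 2007501 to 2011000, all 7 windows rose, from 110 ± 23.8 RPM (SD, n = 2) to 2034 RPM, 18.6-fold higher. A smaller increase was measured on the minus strand from 1997501 to 1999000, where 3 windows rose from 32.7 ± 4.65 RPM (SD, n = 2) to 166 RPM, 5.08-fold higher. At the other locus, the 4 minus-strand windows went from 31.1 ± 1.18 RPM (SD, n = 2) to 853 RPM, 27.4-fold higher. These 4 stretches were made by joining called windows of 1 strand, so their increase follows from the calls. Each was higher in the mutant than in both wild-type libraries. Distinct start positions, unscaled, differed less. They numbered 108 and 127 in wild type 1 and 2 against 534 in the mutant from 2000501, and 56 and 84 against 269 from 2007501. From 1997501 they numbered 33 and 39 against 72, and from 4742001 they numbered 30 and 39 against 151.

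**Figure D2:**
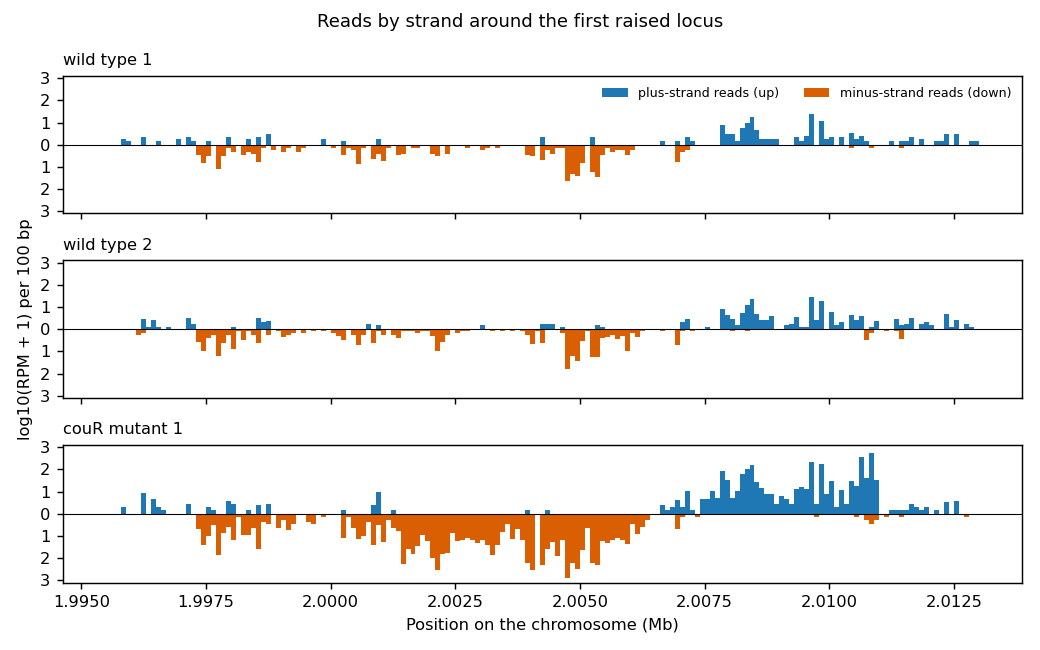
Reads per 100 bp from 1.9955 to 2.013 Mb in each library, as log10(RPM + 1), with plus-strand reads drawn upward in blue and minus-strand reads drawn downward in orange. The mutant shows more minus-strand reads from 2000501 to 2006000 and more plus-strand reads from 2007501 to 2011000 than either wild-type library.

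The 12 windows with the largest called increases had log2 fold changes from 4.16 to 7.74, and 8 of them lay at the larger locus. The highest was the plus-strand window 2010501 to 2011000, with 7 and 23 reads in wild type 1 and 2 and 2115 in the mutant (log2 fold change 7.74 ± 0.48 SE, adjusted p = 9.34e-53, limma-voom). With reads of the same position counted once, its log2 fold change was 3.62 ± 0.64 (SE), and the other named windows that kept the call were at 1.85 to 3.20. In the main test, with all reads counted, the other 6 raised plus-strand windows of this stretch had log2 fold changes of 2.64 to 3.74. In the mutant, plus-strand reads of the stretch ended at 2010926, and the next plus-strand read began at 2011193. The 1000 bp that follow, 2011001 to 2012000, held 3.18 and 7.21 RPM in wild type 1 and 2 and 6.05 RPM in the mutant.

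On the minus strand, the window 2004001 to 2004500 had 22 and 27 reads in wild type 1 and 2 and 1280 in the mutant (6.25 ± 0.41 SE, adjusted p = 1.04e-48, limma-voom). The window 2002001 to 2002500 had 14, 50 and 1216 reads (5.95 ± 0.40 SE), and 2001001 to 2001500 had 21, 13 and 436 (5.34 ± 0.44 SE). The most abundant raised window, 2004501 to 2005000, was at 93.5 ± 11.2 RPM in the wild type (SD, n = 2) and 1304 RPM in the mutant. Some wild-type windows here held few reads. The windows 2003001, 2003501, 2001501 and 2002501 had 6, 10, 8 and 5 reads over both wild-type libraries against 297, 438, 328 and 160 in the mutant. Their ratios of scaled reads were 147 (exact 95% counting interval 66.9 to 405), 130.5 (70.3 to 274), 122 (61.2 to 285) and 95.3 (40.002 to 298). The fitted log2 fold changes of windows 2003001, 2002501, 2002001 and 2001001 were 7.22, 6.36, 5.95 and 5.34. Without wild type 2 they were 6.27, 6.97, 6.62 and 4.57, and without wild type 1 they were 7.75, 6.01, 5.45 and 5.87, with no test in either case.

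At the smaller locus, the windows 4742001, 4742501, 4743001 and 4743501 on the minus strand had log2 fold changes of 4.86 ± 0.39, 4.80 ± 0.39, 4.66 ± 0.40 and 4.16 ± 0.79 (SE). Their reads in the mutant numbered 623, 657, 480 and 72. The largest adjusted p among them was 5.72e-05 (limma-voom), for 4743501. That window was not called by the negative binomial Wald test (log2 fold change 4.17, adjusted p = 0.0562), and its adjusted p ranged from 1.09e-08 to 0.997 over the alternatives.

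**Figure D3:**
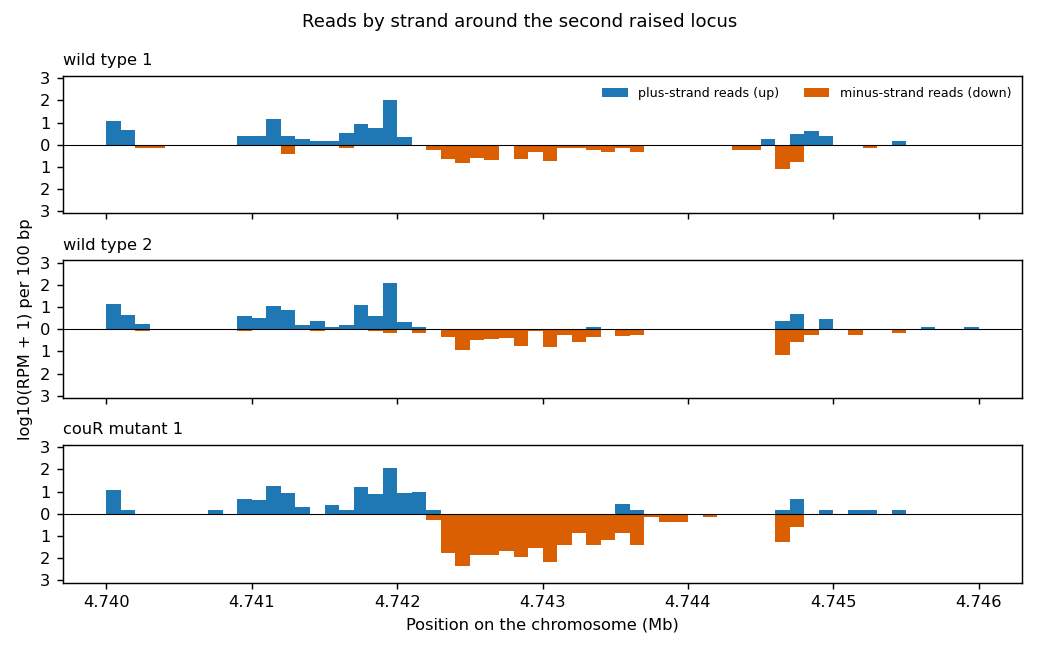
Reads per 100 bp from 4.74 to 4.746 Mb in each library, as log10(RPM + 1), with plus-strand reads drawn upward in blue and minus-strand reads drawn downward in orange. Minus-strand reads from 4742001 to 4744000 are higher in the mutant than in either wild-type library.

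Outside these loci, 2 windows rose, and they are named after their values were seen: 3200501 to 3201000 on the minus strand (1.36 ± 0.33 SE, adjusted p = 0.0112, limma-voom) and 4265501 to 4266000 on the plus strand (1.39 ± 0.33 SE, adjusted p = 0.0103, limma-voom). A single position held 55.6%, 58.0% and 54.1% of the reads of the first window in wild type 1, wild type 2 and the mutant, and 81.5%, 81.3% and 84.7% of those of the second. With reads of the same position counted once neither passed, with log2 fold changes of 0.81 and 0.51. Neither passed when scaled to all mapped reads (0.98 and 1.01, adjusted p = 0.958 for both, limma-voom) or without TMM (1.24 and 1.27, adjusted p = 0.102 and 0.323, limma-voom). Over all alternatives their adjusted p ranged from 0.00215 to 0.958 and from 0.00446 to 0.997. Without wild type 2 the first was at 0.88, and without wild type 1 it was at 1.82.

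No window was called lower by limma-voom. At an unadjusted p under 0.05, 41 windows were lower and 184 higher, where 464 in all would pass by chance. The shortfall does not show that other windows were unchanged. Spread came only from the wild-type pair, which differed at least 2-fold in 138 windows, against 101 between wild type 1 and the mutant. The lower count at an unadjusted p under 0.05 ranged from 23 to 256 over the alternatives. It was 168 when scaled to all mapped reads, 150 by the negative binomial Wald test and 256 with limma on log2(RPM + 1). The negative binomial Wald test called 1 lower window, and limma on log2(RPM + 1) called 3, with or without robust estimation. The 5 lower windows with the smallest p were 3710001 plus at -1.84 ± 0.52 (SE, adjusted p = 0.109, limma-voom), 1784001 plus at -1.90 ± 0.66, 2595001 minus at -1.77 ± 0.70, 158501 plus at -1.53 ± 0.61 and 160501 plus at -1.39 ± 0.56. Window 3710001 was called lower by limma on log2(RPM + 1) (adjusted p = 0.00161, robust 0.00329) and by the negative binomial Wald test (adjusted p = 0.0194), and 1784001 by limma on log2(RPM + 1) (adjusted p = 0.00815, robust 0.0153). Over all alternatives their adjusted p ranged up to 0.997 and 0.99997. Of 33 simulated 8-fold decreases, limma-voom called 12 and the negative binomial Wald test called 20, with 1 false call each. Decreases of that size could thus go uncalled by either test at this depth, and more often by limma-voom.

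With 1 mutant library, the spread of the mutant was not measured, and setting wild type 2 apart from the other libraries called 334 windows, 7 of them at least 4-fold, against 25 at least 4-fold for the mutant. Wild type 2 was there set against a pair that held the mutant, so the raised loci can enter its counts. The wild-type libraries themselves differed at least 4-fold in 2 of the windows with at least 50 reads. Without wild type 2 the top window was at 8.37, without wild type 1 at 7.35, and with reads of the same position counted once 16 of the 25 windows at the loci were still called. The 9 that were not included 5 of those named, the minus-strand windows 2001501, 2002501, 2003001, 2003501 and 4743501, whose log2 fold changes were then 3.85, 4.20, 4.05, 3.99 and 2.76. The other 4 were 1998001, 1998501 and 2000501 on the minus strand and 2009001 on the plus strand, at 1.03, 2.06, 0.90 and 2.48.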

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

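Repeated windows lie outside the comparison of windows, and the mutant had more of its reads there than the controls. The share was 73.0% in the mutant, against 68.0% in wild type 1 and 67.4% in wild type 2. The repeated windows of both large loci held more in the mutant. At 4992001 to 4998000 the share was 37.2% against 35.0% and 34.5%. At 5246001 to 5252000 it was 35.8% against 32.9% and 32.7%, without the plus-strand window 5251501 to 5252000, which was not called repeated. Reads with equally good places can be divided between the 2 loci, so these are not separate observations. The Wilson intervals do not overlap but cover counting error only, and the difference was not tested between genotypes. With reads of the same position counted once, the shares were 6.44% and 6.08% in wild type 1 and 2 and 6.98% in the mutant.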

How the results depend on the processing

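The increase at the 2 loci was found under every alternative that gave a test, with 15 to 37 windows called there, and no named window reversed. The tests with other methods, window sizes or positions, at least 30 reads in 1 library and scaling without TMM were chosen after seeing the data. With reads of the same position counted once, 16 windows were called higher, 16 of them at the loci and 0 elsewhere, and 6 windows with 50 reads were at least 4-fold higher against 25 as reported. That setting tests 5139 windows. With 1000 bp windows, 17 were called higher, 15 at the loci, and 14 were at least 4-fold higher; with 200 bp windows 40 were at least 4-fold higher. Calls outside the loci, 2 as reported, were 0 when scaled to all mapped reads or without TMM, 6 and 5 with limma on log2(RPM + 1) plain and robust, 4 with 200 bp windows and 1 with windows shifted by 250 bp. Lower calls, 0 as reported, were 3 with limma on log2(RPM + 1) plain and robust, 1 by the negative binomial Wald test, 2 with 200 bp windows and 1 with shifted windows. Windows with 50 reads at least 4-fold lower, 0 as reported, were 5 when scaled to all mapped reads, 2 without TMM, 1 with at least 30 reads, 2 by the negative binomial test, 4 with 200 bp windows and 1 with shifted windows. Scaling to all mapped reads moved the median log2 fold change of all windows to -0.40, and scaling without TMM to -0.14. Leaving out a wild-type library leaves values with no test: 24 windows at least 4-fold higher either way, and 0 to 3 at least 4-fold lower, 3 without wild type 1. The cause of these changes was not tested. No paired analysis was possible because the mutant has 1 library, and its title gives no replicate number. The planned edgeR and DESeq2 fits are not reported here, since both were kept for tables deposited as counts; edgeR was run once on these windows while exploring them. Alternatives for couR, the coumarate locus, gene lists and strand shares were not run. The 12 named higher windows gave 155 of 168 values on the same side of the threshold or within the replicate spread. Of the others, 6 moved by more than that spread without wild type 2, and 7 lost the call: 5 with positions counted once, 2002501 when scaled to all mapped reads (log2 fold change 6.02 ± 1.59 SE against 6.36 ± 1.30, adjusted p = 0.0598, limma-voom, range 9.41e-20 to 0.751 over its alternatives) and 4743501 by the negative binomial test. The 5 named lower windows gave 65 of 70 values on the same side, and 5 became calls.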

Other observations

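Outside repeated sequence, a few windows held many of the reads in every library. The 5 most abundant took 40.3% and 34.0% of those reads in wild type 1 and 2 and 37.1% in the mutant. These are shares of reads, not of RNA, and were not redone with reads of the same position counted once. The highest, 1694501 to 1695000 on the minus strand, took 17.0%, 13.0% and 16.4%, and its change in the mutant did not pass (0.25 ± 0.48 SE, adjusted p = 0.998, limma-voom). The next, 3317501 to 3318000 on the minus strand, took 11.7%, 10.9% and 10.7%. The fourth, 5251501 to 5252000 on the plus strand, lies within the repeated locus ending at 5252000, but was not called repeated because no more than 50% of its reads had mapping quality 0.

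No stretch without mutant reads stood out near the raised loci. On the plus strand, 1097172 to 1098284 held no mutant read and 56 wild-type reads, 22 in wild type 1 and 34 in wild type 2. In all, 17 stretches without mutant reads held at least 40 wild-type reads, and 0 of them lay within 5000 bp of either locus. Some were only 2, 3 or 6 bp long. Some windows at the loci held few wild-type reads, such as 1 and 4 at 2002501 to 2003000 on the minus strand. A short loss there could not reach 40 reads, so the search cannot exclude one. Opposite the raised strands, the mutant had 96 reads against 14733 on the raised strands, or 0.65%, against 3.23% and 3.76% in wild type 1 and 2. Their level was higher in the mutant, at 44.7 RPM against 10.7 and 14.4 RPM in wild type 1 and 2, a difference that was not tested.

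For the tests that follow, scaling, the splits of the libraries, the strand comparison in wild type 2 and the order of blocks were chosen after the result was seen; thinning and counting positions once were not. The increase at the 2 loci was set against technical explanations and against the genotype. Stacks of PCR reads alone would lose most calls when positions are counted once, and 16 of 25 remained. A scaling error alone was expected to leave a small change when all mapped reads set the scale, and the smallest log2 fold change was 1.70. That scale moves all windows by nearly the same amount (median from -0.016 to -0.396), so this value could be foreseen. It shows only that this change of scale does not remove the increase. Of 3 ways to set 1 library apart, 2 called at least 27 windows, the mutant itself with 27 and wild type 2 with 334. The calls of the mutant were larger, with a median absolute log2 fold change of 3.74 against 0.71 for wild type 2. With 3 ways, a share under 0.05 cannot be reached, so chance stays open. The genotype and the lane stay open, since each library had a lane of its own.

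Wild type 2 stood apart, with 334 calls (101 higher, 233 lower, median absolute log2 fold change 0.71) against 6 for wild type 1, which points to a structure of the samples that was not identified. In both splits the other libraries included the mutant, so the raised loci can enter these calls. Thinned to 2268637 reads per library in 1 random draw, 83 calls for wild type 2 remained, against 28 for the mutant, so greater depth may account for part, though thinning also lowers power. Genomic DNA stays open: among windows with over 100 reads, the median log2 ratio of the minor strand lay below that of the major by -0.23 (95% bootstrap interval -0.28 to -0.18), against what DNA would give, but the minor-strand share of all reads outside repeated windows was highest in wild type 2, at 2.26% against 2.14% in each of the others. Counting positions once left 2 calls, but that measure saturates in abundant windows and lowers power, so it was not read as a cause although the bound set beforehand was met. No biological explanation was tested, as the labels give the wild-type libraries no difference.

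One hypothesis is that reads run opposite to the RNA. Repeated loci that take most reads from total RNA are candidate rRNA operons, and ASM19577v2 lists 6 rRNA genes in 2 runs. Bacterial rRNA operons carry the shorter 16S gene before the longer 23S gene. In both repeated loci the longer block (3600 and 3700 bp) lay at lower coordinates than the shorter (1700 bp), and at least 99.96% of reads were on the plus strand, which is consistent with RNA read from the minus strand. If so, the raised RNA at 2000501 to 2006000 may come from the plus strand and that at 2007501 to 2011000 from the minus strand, which was not tested at those positions.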
